A study of Mus musculus with 6 samples.

How the data were processed

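Liver tissue of 6 mice was profiled, 3 wild-type controls and 3 ErbB4-/- mice, each on 1 single-colour array. Total RNA was extracted with Trizol, amplified and labelled with biotin with Affymetrix whole-transcript kits, per the labels' protocols. The deposited values are on a log2 scale, 1 value per probe set and array, already processed by the authors. The method of background correction, normalization and summarisation is not given in the sources used here. The log base was taken from the values, whose maximum of 14.4 fits the range of a 16-bit scanner only on a log2 scale. The 6 columns have nearly equal quartiles and no centring per gene, so a level is comparable between arrays but not between probe sets. Array medians were 4.86, 4.83 and 4.83 for control replicates 1 to 3 and 4.84, 4.84 and 4.86 for ErbB4-/- replicates 1 to 3. The design text calls the samples biological replicates.

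The table holds 41345 probe sets. In the platform annotation 23521 of them have 1 gene symbol, 1814 have several and 16010 are unnamed here. A gene was named only from probe sets with 1 symbol, and symbols were compared with the RefSeq genes of assembly GRCm38.p6 by gene identifier, which updated 0 symbols. The build behind the array design is not given in the sources used here, so the RefSeq table served only for names and for which genes neighbour each other. Where a gene had several probe sets, which was the case for 1082 genes, the one with the highest mean over all arrays stood for it. This left 22180 genes. No filter on dim probe sets was applied, and no background signal was used here, so a low log2 value can be background.

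Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, as ErbB4-/- minus control with genotype as the only term, and adjusted by the Benjamini-Hochberg method over the 22180 genes at a threshold of 0.05. Standard errors are those of limma. A permutation test of 3 against 3 arrays cannot give a p below 0.10, so none was used for single genes. Gene lists for pathways, cell types of liver and possible contaminants, 39 in all with 795 members, were tested with camera of limma at its preset correlation of 0.01, adjusted over the 39 lists, then with an estimated correlation and with fry. Of the members, 714 were measured, 5 of them under a newer symbol. The members of a list were also adjusted over the list alone. Some lists share members, such as Vim, Ccn2, Igfbp1 and Cyp39a1. The groups, the test, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. By that rule the named genes are the 12 with the largest rise and the 12 with the largest fall among those that passed, at or above the median level in the higher group and without overlap between the groups. Places left open are filled by the smallest unadjusted p among genes with an absolute log2 difference of at least 0.58, and these are said not to pass. Clone-type, microRNA, small nucleolar and olfactory or vomeronasal receptor symbols were left out. Erbb4, its neighbours and up to 4 members of each list with the smallest p were added. The genes of control replicate 1 and those of distal chromosome 1 were chosen after their values were seen.

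The fit was tested on simulated data with the 22180 genes of ErbB4-/- against control, 200 of them changed. Of these, 26.5% were recovered at a log2 change of 0.58, 60.5% at 1, 95.5% at 2 and 99.5% at 3, with 2 to 14 false calls, and 0 genes were called without a change. The list test called 10 of 10 simulated lists shifted by -0.5 and 1 of 10 lists without a shift. Genes in both simulations vary independently, which real genes do not, and the 200 planted changes ease the adjustment for each other. The shares recovered therefore do not show how many real changes were missed.

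The alternatives were quantile normalization again, centring each array on its median, only genes at or above the median level, the mean of all probe sets of a gene, every row of the table, a trend and robust prior, array weights, the replicate number as a block, the week of dissection as a covariate, leaving out each array in turn, thresholds of 0.01 and 0.1, and 5 or 20 Mb around Erbb4. An alternative pseudocount was planned for linear values and had no use here. Leaving out control replicate 1 and ErbB4-/- replicate 3 together was added after seeing the data. Figures were drawn with matplotlib 3.10.9.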

Results

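Gene expression was measured in liver tissue of 6 mice, 3 wild-type controls and 3 ErbB4-/- mice, with 1 whole-transcript array per mouse. ErbB4 is a receptor tyrosine kinase of the epidermal growth factor receptor family that binds neuregulins. Mice that lack it die as embryos, and per the labels the ErbB4-/- line carries a transgene that supplies the receptor in the heart and was backcrossed to C57BL/6J. Every mouse received 1 injection of DEN, which in this field stands for the liver carcinogen diethylnitrosamine, on postnatal day 14. The treatment protocol gives 32 weeks until dissection for all 6 mice, while the treatment characteristic gives 32, 33 and 34 weeks for control replicates 1 to 3 and 35, 36 and 37 weeks for ErbB4-/- replicates 1 to 3. If the characteristic is right, every ErbB4-/- mouse was older at dissection than every control, and a fit with both terms separates week from genotype only by the weeks within each group. The median log2 value of an array lay between 4.83 and 4.86, and the correlation between arrays, across probe sets, between 0.983 and 0.994. The number of arrays limits the precision, and the median standard error of a difference between the groups was 0.10 on the log2 scale. Differences are given as ErbB4-/- minus control, means with the SD over n = 3 arrays.

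Erbb4 itself, the targeted gene, was read by 1 probe set. It measured 5.42, 5.73 and 5.42 in control replicates 1 to 3 and 4.75, 5.36 and 5.61 in ErbB4-/- replicates 1 to 3. The means were 5.52 ± 0.18 and 5.24 ± 0.44, a log2 difference of -0.28 with a standard error of 0.24, which did not pass (limma, adjusted p = 0.772). The groups overlapped, and without ErbB4-/- replicate 1 the difference was -0.04. The part of the gene that the probe set reads was not examined here, and a mutant allele can leave transcript, so this value does not check the labels. Its neighbours in the annotation did not pass either. Cps1, the first enzyme of the urea cycle, differed by -0.02 (adjusted p = 0.884) and Ikzf2, a zinc finger transcription factor, by 0.19 (adjusted p = 0.764). Among the other receptors of the family, Erbb3 measured 10.08 ± 0.12 in control and 10.23 ± 0.12 in ErbB4-/- liver, and Erbb2 measured 4.97 ± 0.05 and 5.16 ± 0.20. The list of ErbB receptors and ligands, with 14 members measured, had a mean difference of 0.02 and did not pass (camera, adjusted p = 0.865).

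The comparison of ErbB4-/- with control liver asks which transcripts differ between these mice in a carcinogen-treated liver. Loss of the receptor cannot be told apart here from the rescue transgene or other differences of the ErbB4-/- line. Clca3a1, a member of the family of calcium-activated chloride channel regulators, fell 2.30-fold in ErbB4-/- liver. Its log2 value was 6.91 ± 0.06 in control and 5.71 ± 0.07 in ErbB4-/- liver (n = 3 each), a difference of -1.20 with a standard error of 0.06. It was the only gene of 22180 that passed (limma, adjusted p = 0.0463), and the next smallest adjusted p was 0.549. At an unadjusted p under 0.05 there were 1268 genes, 615 higher and 653 lower, where chance alone gives 1109. Leaving out any 1 array ended the call, with a difference between -1.24 and -1.17 and an adjusted p between 0.272 and 0.774. The call was also lost when every row of the table was tested (adjusted p = 0.1005), with the replicate block (adjusted p = 0.780), with the week of dissection as a covariate, at -1.14 (adjusted p = 0.994), and without both control replicate 1 and ErbB4-/- replicate 3 (adjusted p = 0.746).

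The genes named next did not pass, with adjusted p between 0.549 and 0.760 (limma), and are given because their groups did not overlap, with no overlap in 8.33% of all genes against 10% by chance. Hspa1b, an inducible chaperone of the HSP70 family, measured 5.95 ± 0.75 in control and 8.71 ± 0.17 in ErbB4-/- liver, a difference of 2.76 with a standard error of 0.38. Hspa1a, its near-identical neighbour, whose signal on an array is hard to separate from that of Hspa1b, measured 4.71 ± 0.29 and 6.21 ± 1.02. Rarres1, a retinoic acid response gene, differed by 1.30, and Tbc1d30, a Rab GTPase-activating protein, by 1.10. The other genes with higher values were Hsbp1l1 with a difference of 0.88, Neb, which encodes the muscle protein nebulin, with 0.87, Cyp2d37-ps with 0.84, Zfp708 with 0.77, the Wnt receptor gene Fzd8 with 0.73, Rassf3 with 0.63, Prok1 with 0.62 and the junction protein gene F11r with 0.60. Lower values were measured for Ifi204, an interferon-inducible DNA sensor, with 6.00 ± 0.40 against 4.10 ± 0.27 and a difference of -1.90. Csrnp1, a nuclear protein gene of the early stress response, differed by -1.47 and Wsb1, a ubiquitin ligase component, by -1.24. Genes of leukocytes among them were Fcgr3, an Fc receptor of myeloid cells, with -0.95, and Ptprc, the pan-leukocyte antigen CD45, with -0.87. The remaining ones were Postn, the matrix protein periostin, with -0.94, the kinase gene Pim3 with -0.93, the phosphatase gene Dusp23 with -0.88, Rel, a subunit of NF-kappaB, with -0.72, Cyp3a44 with -0.65 and the adhesion receptor gene Adgrg6 with -0.65. Fcgr3, Dusp23, Ifi204 and F11r lie near each other on distal chromosome 1. Among genes with a difference of at least 2-fold and no overlap between the groups, 10 were higher and 77 lower.

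**Figure D1:**
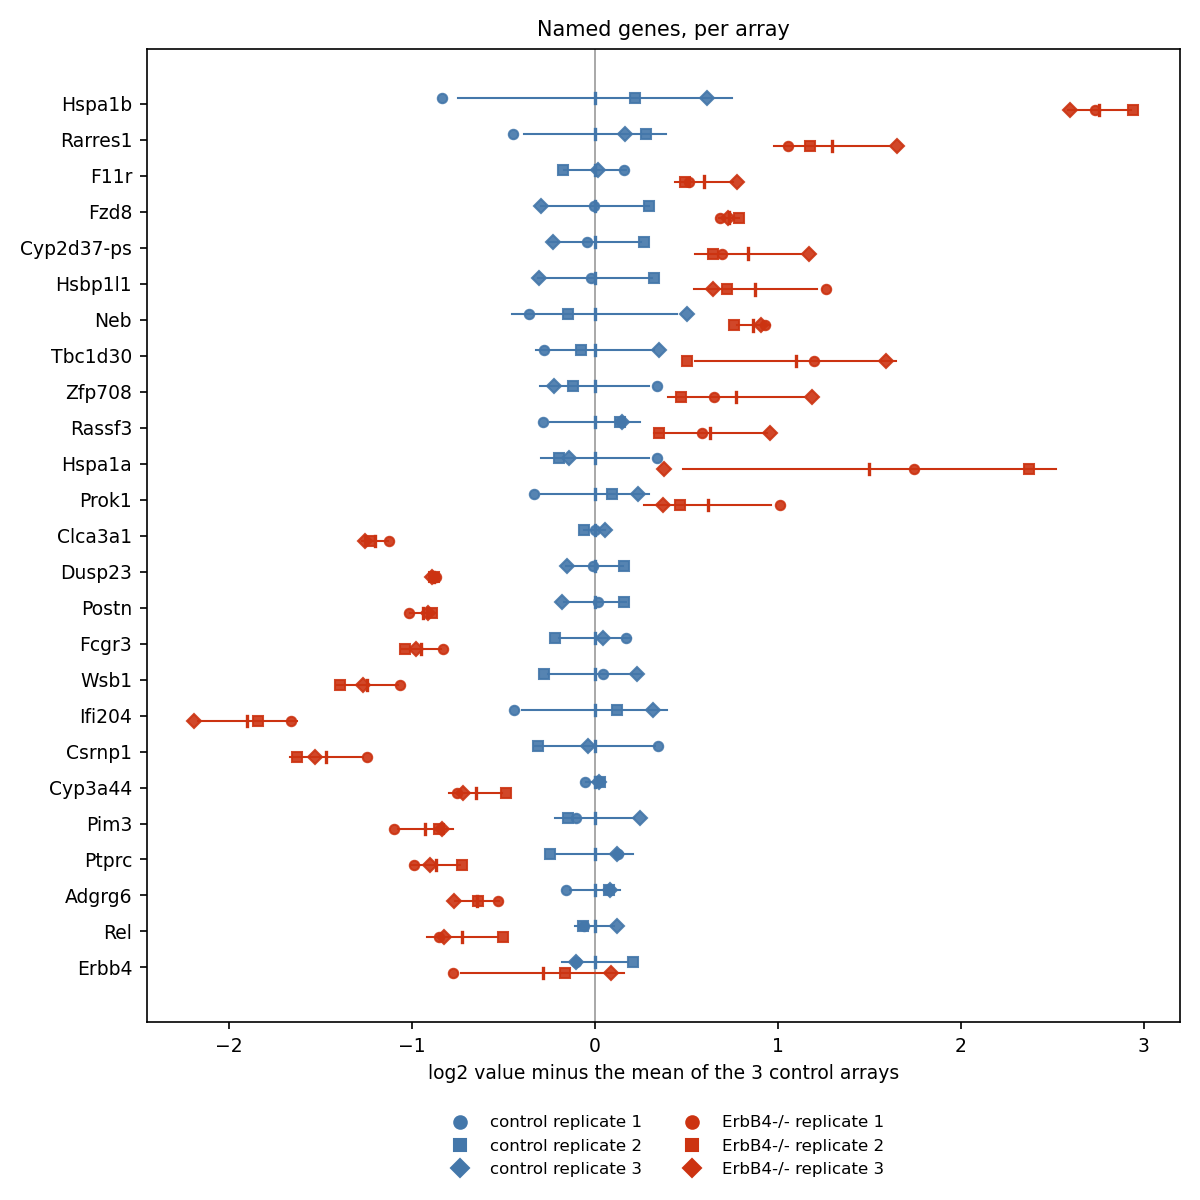
Log2 value of each named gene on each array, minus the mean of the 3 control arrays, for 24 genes and Erbb4. Blue marks are control and red marks ErbB4-/- arrays, with shapes for replicates 1 to 3, short vertical bars for group means and horizontal lines for 1 SD on each side. For Clca3a1 the means lie -1.20 apart, and for Erbb4 the groups overlap.

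Gene lists were tested next, to ask whether cell types or pathways shifted as groups. Markers of Kupffer cells and macrophages, the resident phagocytes of liver, were lower as a list in ErbB4-/- liver. The mean of the 22 markers was 7.49 ± 0.11 in control and 6.88 ± 0.32 in ErbB4-/- arrays (n = 3 each), a mean difference of -0.61, with 20 of 22 lower (camera, adjusted p = 3.5e-11, and adjusted p = 0.516 with an estimated correlation). None passed over all genes, and 6 fell adjusted over the list alone. Among these were the scavenger receptors Cd163, 7.68 ± 0.22 against 6.32 ± 0.61, and Marco, 8.26 ± 0.33 against 6.83 ± 0.63, as well as the lysozyme gene Lyz2, 9.96 ± 0.25 against 9.29 ± 0.23, and the complement gene C1qa, 8.30 ± 0.14 against 7.67 ± 0.30. Neutrophil markers were lower too, with a mean of 6.14 ± 0.95 in control and 4.64 ± 0.16 in ErbB4-/- liver, a mean difference of -1.50 over 13 markers (camera, adjusted p = 4.56e-10, and adjusted p = 0.516 with an estimated correlation). None passed over all genes, and 7 fell adjusted over the list alone, among them Ly6g with a difference of -1.17, Csf3r, the receptor of granulocyte colony-stimulating factor, with -0.61, the calgranulin gene S100a9 with -2.49 and the granule protein gene Ngp with -2.43. Inflammatory cytokines and chemokines had a mean difference of -0.45 and a median of -0.26 over 22 members (camera, adjusted p = 3.84e-07, and adjusted p = 0.516 with an estimated correlation). None passed over all genes, and Vcam1, an adhesion molecule for leukocytes, and the cytokine gene Il1b, 8.93 ± 0.40 against 7.55 ± 0.43, fell adjusted over the list alone. Values of the chemokine genes Cxcl13 and Cxcl1, which did not pass, were 9.43 ± 0.66 against 7.78 ± 0.63 and 9.85 ± 0.43 against 8.08 ± 0.94. With the week as a covariate the macrophage list had a mean of -0.24 (adjusted p = 0.192) and the cytokine list -0.31 (adjusted p = 0.105).

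Lymphocyte and antigen presentation lists did not pass, although some did under other settings. T and NK cell markers had a mean difference of -0.08 over 23 members (camera, adjusted p = 0.107). None passed over all genes, and Ncr1, an activating receptor of NK cells, rose adjusted over the list alone, from 3.95 ± 0.10 to 4.39 ± 0.08, a low signal on these arrays. With the replicate block the T and NK cell list passed (adjusted p = 0.0387). B and plasma cell markers had a mean difference of -0.21 (adjusted p = 0.237), with the immunoglobulin chain genes Ighm at 10.64 ± 0.57 against 9.55 ± 0.70 and Jchain at 8.26 ± 0.63 against 6.73 ± 1.16. Restricting the test to genes at or above the median level gave the B and plasma cell list a mean of -0.65, and it passed there (adjusted p = 0.0130), as it did with every row of the table tested, at -0.43 (adjusted p = 0.0139). The list of MHC class II and antigen presentation had a mean difference of -0.14 (adjusted p = 0.0742), with H2-Ab1 at 9.13 ± 0.57 against 8.82 ± 0.35. Without control replicate 2 its mean was -0.27 and it passed (adjusted p = 6.41e-04), and without ErbB4-/- replicate 1 its mean was -0.19 and it passed (adjusted p = 0.0463). Leaving out ErbB4-/- replicate 3 moved it the other way, to -0.065 (adjusted p = 0.445). Interferon response genes had a mean difference of 0.06 over 27 members (adjusted p = 0.614), with the peptide transporter gene Tap1 at 7.60 ± 0.12 against 8.05 ± 0.28. No member of these 4 lists other than Ncr1 passed adjusted over the list alone.

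**Figure D2:**
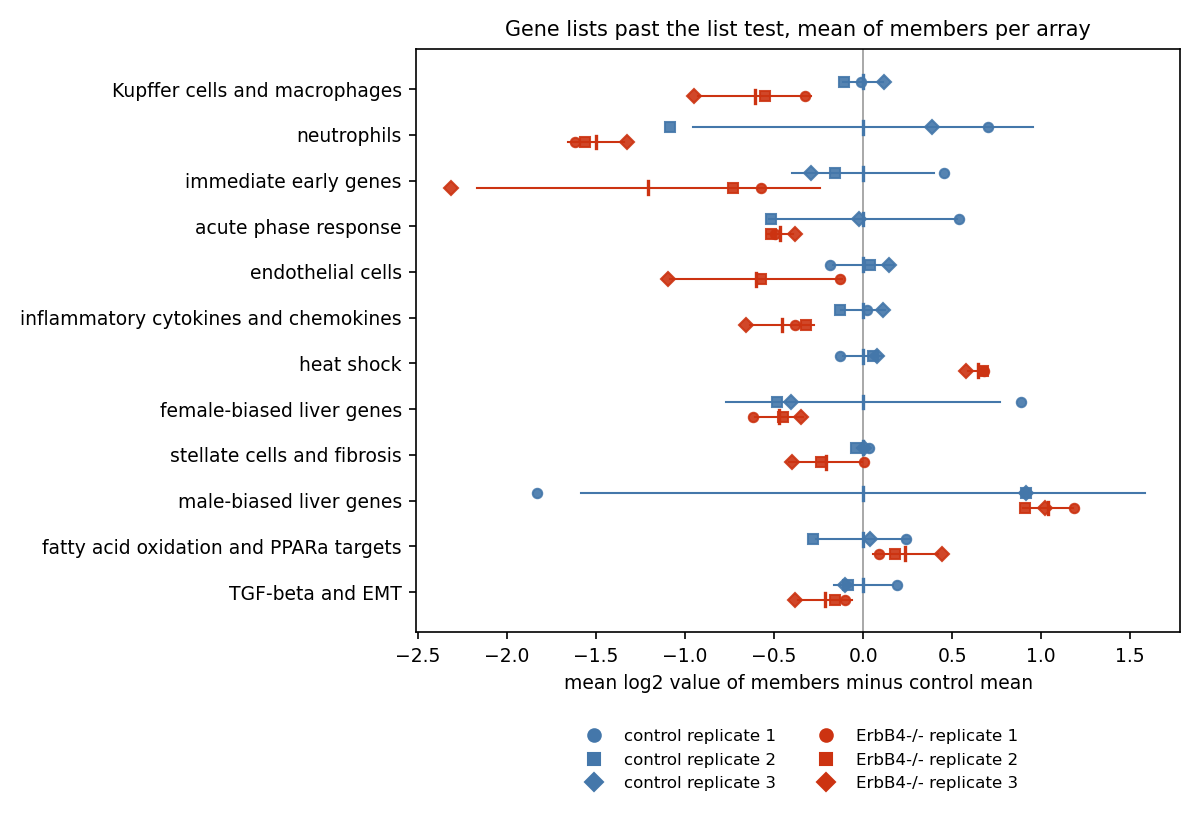
Mean log2 value of the members of each gene list on each array, minus the mean of the 3 control arrays, for the 12 lists that passed the list test with its preset correlation. Blue marks are control and red marks ErbB4-/- arrays, with shapes for replicates 1 to 3, short vertical bars for group means and horizontal lines for 1 SD on each side. In the male-biased list control replicate 1 lies far below the other 5 arrays, and in the immediate early list ErbB4-/- replicate 3 lies far below the rest.

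Acute phase genes, which hepatocytes induce during inflammation, were lower as a list in ErbB4-/- liver. The mean of 25 members was 11.03 ± 0.53 in control and 10.56 ± 0.07 in ErbB4-/- arrays, a mean difference of -0.46 (camera, adjusted p = 3.22e-08, and adjusted p = 0.516 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The C-reactive protein gene Crp measured 12.20 ± 0.09 in control and 11.42 ± 0.30 in ErbB4-/- liver, the metalloreductase gene Steap4 10.43 ± 0.46 and 9.38 ± 0.11, the ceruloplasmin gene Cp 12.74 ± 0.21 and 12.42 ± 0.08, and the hemopexin gene Hpx 13.57 ± 0.17 and 13.32 ± 0.09. The list moved with single control arrays, to -0.20 without control replicate 1 and to -0.72 without control replicate 2, and with the week as a covariate it was -0.13 (adjusted p = 0.217).

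Endothelial markers had a mean of 7.61 ± 0.17 in control and 7.005 ± 0.48 in ErbB4-/- liver, a mean difference of -0.60 over 20 members (camera, adjusted p = 1.3e-07, and adjusted p = 0.516 with an estimated correlation). Among genes of the sinusoidal endothelium, Lyve1 measured 7.89 ± 0.59 in control and 6.32 ± 0.44 in ErbB4-/- liver, Stab1 7.50 ± 0.05 and 7.22 ± 0.17, Fcgr2b 9.91 ± 0.32 and 8.68 ± 0.83, and Gpr182 7.54 ± 0.24 and 6.76 ± 0.57. Markers of stellate cells and fibrosis were lower by -0.21 as a list of 24 (camera, adjusted p = 6.8e-04, and adjusted p = 0.516 with an estimated correlation), with the matrix protein genes Ecm1 at 9.41 ± 0.20 against 8.95 ± 0.15, Dcn at 11.37 ± 0.17 against 10.62 ± 0.38 and Sparc at 7.56 ± 0.15 against 7.07 ± 0.21. The list of TGF-beta and EMT genes was lower by -0.21 over 18 members (camera, adjusted p = 0.00581, and adjusted p = 0.516 with an estimated correlation), with the TGF-beta antagonist gene Skil at 6.93 ± 0.43 against 6.10 ± 0.12 and the matricellular gene Ccn2 at 7.09 ± 0.15 against 6.61 ± 0.23. No member of these 3 lists passed over all genes or adjusted over the list alone. Without ErbB4-/- replicate 3 the endothelial mean was -0.35, the stellate mean -0.12 and the TGF-beta mean -0.13, the last of which no longer passed (adjusted p = 0.142). The TGF-beta call was also lost without control replicate 1, at -0.12 (adjusted p = 0.137), and the stellate mean was -0.32 without ErbB4-/- replicate 1. Without both control replicate 1 and ErbB4-/- replicate 3, removed together after the data were seen, the stellate mean was -0.10 (adjusted p = 0.0847) and the TGF-beta mean -0.034 (adjusted p = 0.638), and neither passed. With the week as a covariate none of the 3 lists passed, with means of -0.13 for the endothelial list (adjusted p = 0.863), 0.11 for the stellate list (adjusted p = 0.388) and 0.22 for the TGF-beta list (adjusted p = 0.266). Cholangiocyte and progenitor markers had a mean difference of 0.07 (adjusted p = 0.533), and YAP and Notch targets -0.10 (adjusted p = 0.112).

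Immediate early genes, the transcription factors and regulators that cells induce within minutes of a stimulus, were lower in ErbB4-/- liver as a list. The mean of 19 members was 8.72 ± 0.40 in control and 7.51 ± 0.96 in ErbB4-/- arrays, a mean difference of -1.21 with 18 of 19 lower (camera, adjusted p = 7.73e-10, and adjusted p = 0.516 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The nuclear receptor gene Nr4a1 measured 9.05 ± 0.69 in control and 7.24 ± 0.51 in ErbB4-/- liver, the stress genes Gadd45b 7.87 ± 0.31 and 7.07 ± 0.23 and Gadd45g 9.46 ± 0.18 and 7.56 ± 0.98, and Ier2 9.71 ± 0.39 and 8.22 ± 1.09. Without ErbB4-/- replicate 3, which stood apart from the other arrays on the first principal component, the mean difference was -0.65 and still passed, without both this array and control replicate 1 it was -0.43 and still passed, and with the week as a covariate it turned to 0.66 (adjusted p = 0.145). Heat shock genes moved the other way, with a mean of 7.65 ± 0.11 in control and 8.29 ± 0.06 in ErbB4-/- liver, a mean difference of 0.64 and a median of 0.28 over 10 members (camera, adjusted p = 1.42e-04, and adjusted p = 0.488 with an estimated correlation). The mean lies above the median because it includes the difference of 2.76 for Hspa1b and that of its neighbour Hspa1a. None passed over all genes, and Hspa1b rose adjusted over the list alone (adjusted p = 0.00447). The cochaperone gene Dnajb1 measured 6.75 ± 0.13 and 7.09 ± 0.22, and the constitutive chaperone gene Hspa8 11.98 ± 0.14 and 12.25 ± 0.17. With the week as a covariate the heat shock mean was 0.56 (adjusted p = 0.145). The unfolded protein response list had a mean difference of 0.06 (adjusted p = 0.653), with the endoplasmic reticulum chaperone gene Hspa5 at 9.14 ± 0.10 against 9.57 ± 0.28, and the NRF2 antioxidant list -0.15 (adjusted p = 0.112), with the haem oxygenase gene Hmox1 at 7.67 ± 0.13 against 6.98 ± 0.39. The NRF2 list passed without ErbB4-/- replicate 1, at -0.26 (adjusted p = 0.00406), and with the replicate block (adjusted p = 0.0387). Leaving out ErbB4-/- replicate 3 moved it the other way, to -0.058 (adjusted p = 0.420).

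Sex-biased liver genes separated 1 control array from all others. The male-biased list had a mean of 9.37 ± 1.58 in control and 10.41 ± 0.14 in ErbB4-/- liver, a mean difference of 1.04 over 19 members (camera, adjusted p = 0.00125, and adjusted p = 0.739 with an estimated correlation). The female-biased list had a mean difference of -0.47 over 21 members (camera, adjusted p = 5.76e-04, and adjusted p = 0.522 with an estimated correlation). Without control replicate 1 the male-biased list differed by 0.12 (adjusted p = 0.926) and the female-biased list by -0.028 (adjusted p = 0.747), so both calls were lost without that array, and they were lost without both this array and ErbB4-/- replicate 3, at 0.13 (adjusted p = 0.947) and -0.090 (adjusted p = 0.167), while without control replicate 2 the female-biased mean was -0.71. With the week as a covariate both calls were lost and both means turned sign, to -0.90 for the male-biased list (adjusted p = 0.105) and 0.30 for the female-biased list, whose test stayed downward (adjusted p = 0.855). In control replicate 1 the steroid dehydrogenase gene Hsd3b5 measured 2.52, against 8.70 to 9.88 on the other 5 arrays, the fatty acid elongase gene Elovl3 7.22 against 11.38 to 13.30, and the fatty acid hydroxylase gene Cyp4a12a 4.09 against 8.43 to 9.50. The female-type cytochrome genes Cyp2b9 and Cyp2b13 measured 12.59 and 10.91 there, against 7.84 to 8.46 and 5.89 to 6.46. Sult3a1, at 5.23 against 2.80 to 3.94, and the dim A1bg, at 4.01 against 3.23 to 3.77, were higher too. Other female-biased genes did not follow, with Cyp2a4 at 9.45 against 8.76 to 9.54 and Cyp3a44 at 6.92 against 6.23 to 7.01. The female-type pattern of this array was thus partial. The Y-linked genes of this array lay at the level of the others, with Eif2s3y at 8.85 against 8.77 to 9.08 and Kdm5d at 6.91 against 7.02 to 7.07, and Xist measured 3.54 against 3.32 to 3.60. No member of the male-biased list passed over all genes or adjusted over the list alone. Cyp3a44 fell adjusted over the female-biased list alone (adjusted p = 0.00772), from 6.98 ± 0.05 to 6.33 ± 0.15, but not over all genes, and its signal is hard to separate from that of related Cyp3a genes. The list of sex chromosome genes had a mean difference of -0.02 (adjusted p = 0.734), and the growth hormone and IGF list had a mean of -0.07, a median of 0.14 and an upward test (adjusted p = 0.653).

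**Figure D3:**
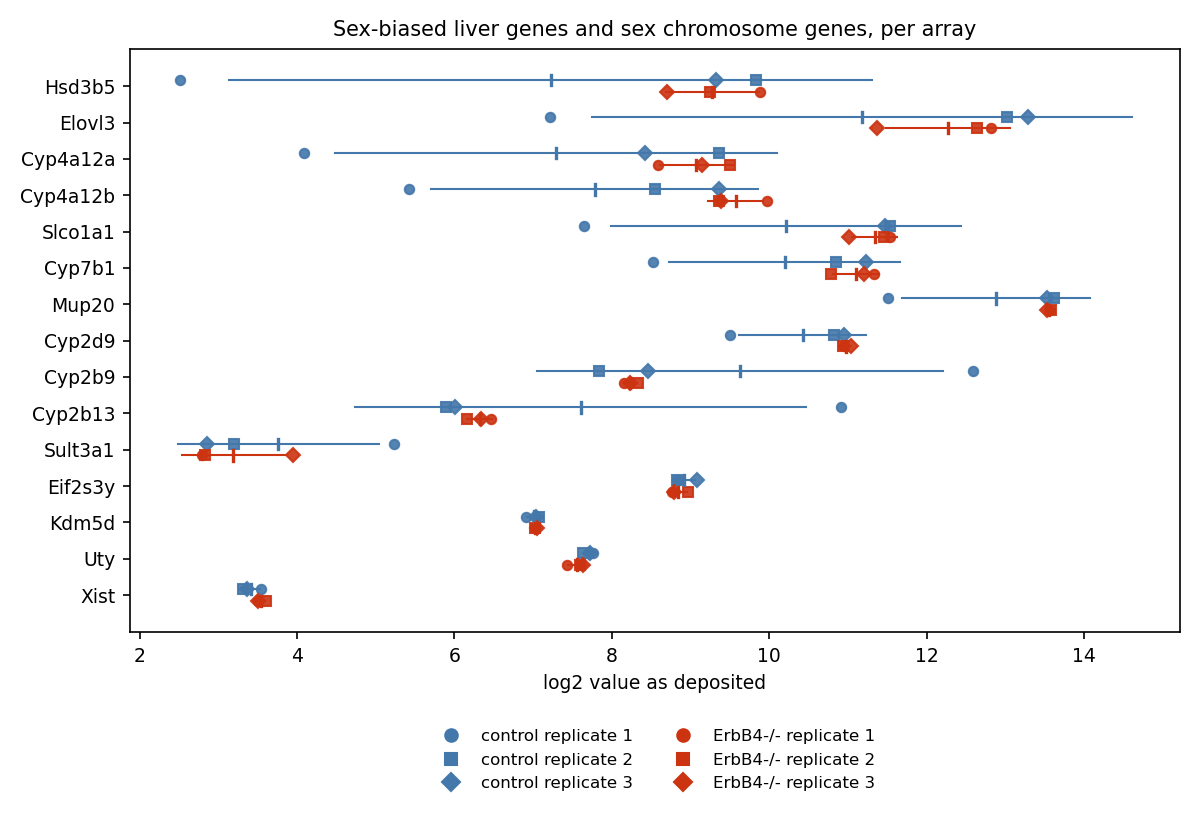
Log2 value as deposited of selected sex-biased liver genes, without Cyp2a4, Cyp3a44 and A1bg, and of 4 sex chromosome genes on each array. Blue marks are control and red marks ErbB4-/- arrays, with shapes for replicates 1 to 3, short vertical bars for group means and horizontal lines for 1 SD on each side. Control replicate 1 lies apart for Hsd3b5, at 2.52 against 8.70 to 9.88 elsewhere, and within 0.16 of the other arrays' mean for Eif2s3y, Kdm5d and Uty.

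Of the metabolic lists, fatty acid oxidation and PPARa targets was higher in ErbB4-/- liver. Its mean was 9.01 ± 0.26 in control and 9.25 ± 0.18 in ErbB4-/- arrays, a mean difference of 0.24 with 20 of 22 members higher (camera, adjusted p = 0.00242, and adjusted p = 0.516 with an estimated correlation). No member passed over all genes or adjusted over the list alone. The peroxisomal thiolase gene Acaa1b measured 9.85 ± 0.24 in control and 10.39 ± 0.15 in ErbB4-/- liver, the fatty acid binding protein gene Fabp1 12.50 ± 0.12 and 12.71 ± 0.07 and the pantetheinase gene Vnn1 7.74 ± 0.68 and 8.72 ± 0.39, while the hormone gene Fgf21 measured 5.95 ± 0.18 and 5.34 ± 0.41. The call was lost without control replicate 2, at 0.098 (adjusted p = 0.0795), without ErbB4-/- replicate 3, at 0.14 (adjusted p = 0.120), and with the week as a covariate, at 0.13 (adjusted p = 0.817), and the mean was 0.36 without control replicate 1. Fatty acid and triglyceride synthesis had a mean difference of 0.0028 (adjusted p = 0.758), but passed without control replicate 2 at 0.15 (adjusted p = 0.0120). Cholesterol synthesis had a mean difference of -0.15 (adjusted p = 0.217), and passed without ErbB4-/- replicate 2 at -0.28 (adjusted p = 0.0193) and with the replicate block (adjusted p = 0.0378). Bile acid synthesis and transport had a mean difference of 0.11 (adjusted p = 0.823), with the oxysterol hydroxylase gene Cyp39a1 at 8.77 ± 0.55 against 7.23 ± 0.60. Gluconeogenesis and glucose handling had a mean difference of -0.14 (adjusted p = 0.204), with Igfbp1, a fasting-induced binding protein of insulin-like growth factors, at 11.39 ± 0.56 against 9.79 ± 0.46. This list passed without control replicate 2 at -0.24 (adjusted p = 0.0173), while without control replicate 1 its mean was -0.061 (adjusted p = 0.685). Xenobiotic metabolism had a mean difference of -0.16 (adjusted p = 0.112), with the drug-metabolising cytochrome gene Cyp3a11 at 12.08 ± 0.10 against 11.72 ± 0.11. This list passed with the replicate block (adjusted p = 0.0302), while without control replicate 1 its mean was -0.033 (adjusted p = 0.228).

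Lists on growth, damage and tumours did not pass. The p53 target list had a mean difference of -0.20 over 26 members (camera, adjusted p = 0.120), and passed without control replicate 2 at -0.25 (adjusted p = 0.0410). Leaving out ErbB4-/- replicate 3 moved its mean the other way, to -0.13 (adjusted p = 0.295). No member passed over all genes, and Trp53inp1, a stress-induced p53 cofactor, fell adjusted over the list alone (adjusted p = 0.0484), from 10.62 ± 0.40 to 9.15 ± 0.36. The cell cycle list had a mean difference of -0.03 over 38 members (adjusted p = 0.112), with the proliferation marker Mki67 at 5.51 ± 0.10 against 5.33 ± 0.11, and passed without control replicate 2 at -0.056 (adjusted p = 0.0418). Liver tumour markers had a mean difference of 0.01, a median of 0.05 and a downward test (adjusted p = 0.706), with the protease inhibitor gene Slpi at 6.15 ± 0.34 against 5.43 ± 0.07. No member of the cell cycle and tumour marker lists passed over all genes or adjusted over the list alone.

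Hepatocyte lists lay close to 0. The abundant hepatocyte proteins had a mean difference of 0.0018, a median of -0.02 and a downward test (camera, adjusted p = 0.620). Pericentral genes had a mean of -0.02, a median of 0.0034 and a downward test (adjusted p = 0.653), and periportal genes had a mean of -0.08 (adjusted p = 0.729). The pericentral gene Ahr, the aryl hydrocarbon receptor, measured 9.17 ± 0.15 in control and 8.45 ± 0.33 in ErbB4-/- liver and did not pass. Circadian clock genes had a mean of 0.03, a median of 0.16 and a downward test (adjusted p = 0.823). Clock genes that peak at opposite times offset each other in such a mean, so it does not test the time of dissection. Between arrays the list mean was 7.46 on control replicate 1 and 7.63 on ErbB4-/- replicate 3, against 7.05 to 7.15 on the others. Among lists for tissue carried along at dissection, skeletal and heart muscle had a mean difference of 0.04 (adjusted p = 0.520), pancreatic acinar cells 0.04 (adjusted p = 0.706) and erythroid cells, with 2 members measured, -0.08 (adjusted p = 0.734). Adipose tissue had a mean of -0.02, a median of 0.05 and an upward test (adjusted p = 0.718). Over all 39 lists, 12 passed with camera's preset correlation, 9 lower and 3 higher. With an estimated correlation 0 passed, the smallest adjusted p being 0.488, and with fry's directional test 0 passed, the smallest being 0.172. Fry's mixed test, which looks for changes of either sign, passed T and NK cells (adjusted p = 0.00318), heat shock (adjusted p = 0.00356) and the growth hormone and IGF axis (adjusted p = 0.0408). Adjusted over each list alone, 2 members were higher and 17 lower in total, and over all genes 0 list members passed, with 1268 of all genes at an unadjusted p under 0.05 (limma).

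The region around Erbb4 on chromosome 1 was examined because DNA of the strain in which a mutant allele was made can stay linked to it through backcrossing. Of 169 tested genes within 10 Mb on each side, 0 passed (limma) and 5 had an unadjusted p under 0.05, which is 2.96% against 5.74% of the other genes (two-sided Fisher's exact test, p = 0.135). Their median difference was 0.03, and the region did not pass camera's list test. The smallest unadjusted p in the region was that of Adam23, which did not pass adjustment. Within 5 Mb the share was 3.12% of 64 genes (two-sided Fisher's exact test, p = 0.586), and within 20 Mb it was 6.73% of 297 genes (two-sided Fisher's exact test, p = 0.449).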

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

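The removal of both control replicate 1 and ErbB4-/- replicate 3 was chosen after the data were seen, and the other alternatives were planned. Clca3a1 kept its direction in all 16 alternatives, and 1 gene passed after quantile normalization again, median centring, the level filter, averaging of probe sets, the trend and robust prior and array weights. The count was 0 with every row tested, with the week as a covariate, with both arrays removed and at an adjusted p under 0.01, and 0 to 0 without 1 array at a time, and the count of genes with at least a 2-fold change was likewise 0 with every row tested, the week covariate and both arrays removed, and 0 to 0 without 1 array. Fewer arrays or more tests tend to raise the adjusted p, though not in every case. For the week covariate the cause was not tested. The week in the characteristic rises with sample order and so largely parallels genotype, which leaves the fit little to separate them by. Calls lost or signs turned under it therefore do not show an effect of age. The labels do not state that replicate numbers pair the mice. Same-numbered arrays deviated with correlations of -0.10, 0.03 and -0.05 across genes, and each correlated better with an array of another number. These values, all near 0, show no pairing but cannot exclude one. With the replicate block the paired fit passed 0 genes, 0 of them with a 2-fold change, and 16 lists. Of 39 lists, 12 passed as reported, 1 with the week covariate, which was neutrophils, 0 with an estimated correlation and 0 with fry's directional test, 8 without both arrays that stand apart, and 9 to 16 without 1 array. The neutrophil call held in all 16 alternatives of the fit, but its mean ran from -2.04 to -1.15 without 1 array at a time. The list mean was 6.84, 5.06 and 6.53 on control replicates 1 to 3 and 4.52, 4.58 and 4.82 on ErbB4-/- replicates 1 to 3. Control replicate 2 thus lay nearer to the ErbB4-/- arrays than to the other controls. Over lists and alternatives, 543 of 624 values kept sign and side of the threshold, 14 gained a call and 51 turned sign. In all 21 calls were lost, 16 with the sign kept and 5 with the sign turned. With the week of dissection as a covariate the sign turned for ErbB receptors and ligands -0.010, NRF2 antioxidant response 0.16, TGF-beta and EMT 0.22, YAP and Notch targets 0.19, abundant hepatocyte proteins -0.021, adipose tissue 0.0082, bile acid synthesis and transport -0.21, cholesterol synthesis 0.33, circadian clock -0.11, female-biased liver genes 0.30, growth hormone and IGF axis 0.021, immediate early genes 0.66, interferon response -0.017, male-biased liver genes -0.90, stellate cells and fibrosis 0.11, xenobiotic metabolism 0.19 and Cps1 0.030. Without both arrays that stand apart the sign turned for ErbB receptors and ligands -0.0020, YAP and Notch targets 0.0021, cholesterol synthesis 0.014, circadian clock -0.038 and fatty acid and triglyceride synthesis -0.018. Among genes at or above the median level the sign turned for cholangiocytes and progenitors -0.29, liver tumour markers -0.058, pancreatic acinar cells -0.012 and skeletal and heart muscle -0.00060. With array weights the sign turned for circadian clock -0.025. With every row tested the sign turned for liver tumour markers -0.0095. After quantile normalization again the sign turned for pericentral hepatocyte genes 0.0011 and Cps1 0.014. Over the fits without 1 array, values that turned sign ranged as follows: abundant hepatocyte proteins -0.014 to 0.013, adipose tissue -0.066 to 0.044, bile acid synthesis and transport -0.010 to 0.21, cholangiocytes and progenitors -0.011 to 0.11, cholesterol synthesis -0.28 to 0.061, circadian clock -0.16 to 0.15, fatty acid and triglyceride synthesis -0.088 to 0.15, growth hormone and IGF axis -0.12 to 0.0018, interferon response -0.027 to 0.11, liver tumour markers -0.087 to 0.074, periportal hepatocyte genes -0.17 to 0.014, sex chromosome genes -0.047 to 0.012, skeletal and heart muscle -0.012 to 0.082, unfolded protein response -0.049 to 0.11, Cps1 -0.037 to 0.0015. The cause was not tested. Signal over background was not used here, so the alternatives do not show what dim probe sets limit.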

Other observations

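Tests on the distal part of chromosome 1, on the share of cell types, on handling and on control replicate 1 were chosen after the results were seen, while the splits of the arrays and the check for a single array were not. A stretch of neighbouring genes on distal chromosome 1, from Rgs4 to Adss in the annotation, held more small p-values than any other place in a scan of 848 windows of 50 neighbouring genes. Of 125 tested genes in it, 13 had an unadjusted p under 0.01, against 1.35 at the rate of all genes. The stretch was chosen for these p-values, so that contrast is partly built in. None of the 13 passed adjustment over all genes (limma, adjusted p between 0.549 and 0.760). Lower values were measured for genes of the interferon-inducible Ifi200 family, with log2 differences of -1.90 for Ifi204, -0.99 for Ifi207, -0.96 for Ifi203-ps and -0.76 for Ifi205, while Ifi202b of the same family was higher by 1.17, at 2.94 ± 0.13 in control and 4.11 ± 0.21 in ErbB4-/- liver (n = 3 each), a dim signal. Signals of related Ifi200 genes can overlap on an array. The Fc receptor genes Fcgr3 and Fcgr4 differed by -0.95 and -1.14, the unfolded protein response sensor gene Atf6 by -0.47, the C-reactive protein gene Crp by -0.78, the phosphatase genes Dusp23 and Dusp12 by -0.88 and -0.44, Nit1 by -0.20 and F11r by 0.60. Crp was also given above as an acute phase gene. Fcgr2b, given above as an endothelial gene, lies in the stretch too and differed by -1.23, with a p above 0.01. Between Erbb4 and this stretch lay 630 tested genes, so it is not next to the targeted gene.

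For this stretch, placing the p-values at random along the genome gave a run of 50 neighbouring genes with as many under 0.01 as the 7 observed in a share of 0.001 of 10000 placements, which argues against chance placement, though neighbours of 1 family do not vary independently. The highest count on another chromosome was 4. A loss of leukocytes stays open for the lower genes as a set. Their mean shift differed from that of the Kupffer markers by -0.25 with a standard error of 0.15. That mean covers 11 genes and mixes the Fc receptor genes with Crp, given above as an acute phase gene, which hepatocytes induce. It therefore does not show that fewer leukocytes could lower each of them. The 2 genes above all controls on all 3 ErbB4-/- arrays do not exclude such a loss, since the genes were picked by their p-values. A candidate explanation is DNA of another mouse strain on distal chromosome 1 in the ErbB4-/- line, for example beside the rescue transgene, whose place is not given in the sources used here. The 13 genes with p under 0.01 neither support nor exclude it, because they defined the stretch and the arrays carry no genotype, and an effect of ErbB4 on these genes stays open as well.

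The Kupffer, neutrophil, cytokine, acute phase, endothelial and immediate early lists were lower in ErbB4-/- liver with camera's preset correlation, while T and NK cells and B and plasma cells did not pass. With an estimated correlation (adjusted p = 0.516 for each of the former) or fry's directional test none of them passed. Of these 6 lists, 6 kept an adjusted p under 0.05 (camera, preset correlation) without each array in turn, the highest being 0.0014. They are the lower lists with the smallest p, so a kept call is only weak evidence against a single array as its sole origin. The acute phase mean went from -0.46 to -0.20 without control replicate 1. Without ErbB4-/- replicate 3 the immediate early mean went from -1.21 to -0.65 and the endothelial mean from -0.60 to -0.35. Of the other lower lists, female-biased genes lost their call without control replicate 1. TGF-beta and EMT lost it without control replicate 1 and without ErbB4-/- replicate 3. Handling at dissection, which induces immediate early genes within minutes, may lie behind the immediate early shift of -1.21 (SE 0.60), and it stays open for the Kupffer genes too, whose shift of -0.61 (SE 0.19), or -0.24 (adjusted p = 0.192) with the week as a covariate, is the pattern itself and no separate test, and the labels record no handling. A lower share of all non-parenchymal cells would lower their markers alike. At or above the median level the Kupffer shift exceeded that of T and NK cells by -0.62 (SE 0.28), of stellate cells by -0.45 (SE 0.11) and of cholangiocytes by -0.43 (SE 0.18). It matched that of B and plasma cells within error, at -0.069 (SE 0.23). These comparisons rest on only 5, 19, 2 and 5 members of the other lists. Over all members, dim ones included, the differences were -0.53 (SE 0.21), -0.40 (SE 0.095), -0.68 (SE 0.14) and -0.40 (SE 0.19). The Kupffer shift also matched that of the endothelial list, at -0.053 (SE 0.13) over 18 members and -0.0090 (SE 0.13) over all members. Endothelial cells are among the 6 lower lists, so that match is part of the pattern and no separate test. A lower share of non-parenchymal cells therefore stays open, as do the time and the age at dissection and ErbB4 itself.

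Control replicate 1 carried the partly female-type pattern of liver genes described above. Hsd3b5 differed by -6.88 and Cyp2b9 by 4.39 from the mean of the other 5 arrays, while Cyp2a4 and Cyp3a44 lay within their range. A female mouse, or female RNA under this title, is argued against by the Y-linked genes, whose mean differed from that of the other 5 arrays by -0.0057, against an SD of 0.07 among those arrays. A failed array, in the sense of lost signal, had no separate test. The female-biased list was higher by 1.35 than on the other 5 arrays, against an SD of 0.10 among them. That rise is part of the pattern itself, so it decides nothing about the array. No biological explanation was tested, since the design names none for a single control mouse.

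The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1 gene, and the highest of the others 0, so that 1 of 10 splits reached the real count. The same numbers, 1 for the real split and 0 for the highest other, with 1 of 10 reaching it, hold for genes with at least a 2-fold change. For lists the real split passed 12 and the highest other 16, and 3 of 10 splits passed as many as the real one, so the list counts follow structure among the arrays other than genotype too. At an unadjusted p under 0.05 the real split had 1268 genes and the highest other 855.

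The 16010 unnamed probe sets held 0 that passed when every row was tested (limma, smallest adjusted p = 0.1005), with 1129 at an unadjusted p under 0.05.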
